A study of Drosophila melanogaster with 4 samples.

How the data were processed

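Chromatin immunoprecipitation followed by sequencing was done for the linker histone H1, which binds the nucleosome where DNA enters and leaves it. The chromatin came from nuclei of heads of adult Oregon-R flies, a wild-type laboratory strain of Drosophila melanogaster. Per the labels, heads were collected from whole adults with sieves, tissue was homogenized and fixed with formaldehyde, and nuclei were lysed with SDS and sonicated before precipitation. The series holds 4 samples, which are 2 H1 ChIP replicates and 2 input samples. The labels tie input replicate 1 to ChIP replicate 1 and input replicate 2 to ChIP replicate 2. They do not say whether the replicates came from separate collections of flies, so a spread between replicates here may be technical, and they give no sex.

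The files used are 3 lists of enriched regions, called clusters below. Each ChIP replicate has its own list, called per sample, and a combined list was made for the replicate set. How the replicates were combined is not given in the sources used here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The caller, its version, its threshold and its filters are not given in the sources used here. Coordinates are those of FlyBase release 5, per the file headers, and are given 1-based. The headers name 14 sequences, which are the main arms 2L, 2R, 3L, 3R, 4 and X, the heterochromatic sequences 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, and the unplaced sequences U and Uextra. The input samples had no list of their own and entered only through the calls of the authors.

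The lists hold 1 value per cluster, which the authors deposited in the score field without a name. It was read, from the values alone, as a log2 enrichment that the authors calculated for each called cluster from ChIP over input reads. Raised as a power of 2, nearly all scores were a whole number divided by a whole number, times 1 constant per list. With whole divisors of at most 2000 and a tolerance of 1e-12, this held for 99.96% of scores in replicate 1, 99.97% in replicate 2 and 99.93% in the combined list. The constants were 1.17, 1.11 and 1.14, and each is known only up to a simple whole-number factor. The divisor in lowest terms is called the reduced input count below. It is not a count the authors gave: shared factors lower it and an uncertain constant can raise it, so it was used as a relative measure of the input reads behind clusters of 1 list. Cutoffs at low reduced input counts, used to leave clusters out, carry the same uncertainty. Counts added to avoid division by 0, if any were used, are not known. Fold enrichment in the text is 2 raised to the deposited score, and no difference in its level between lists was tested. Scores were used to describe, rank and filter clusters, to compare shared with unshared clusters of a list, for a rank and a linear correlation between the replicates, and as the source of the reduced input counts. Library depth is unknown, so no interval that needs it is given.

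Apart from those named below as not fixed, the tests for clusters, replicates, arms, X and position were fixed before the data were examined. So were their main alternatives. Overlap was computed in Python at a minimum of 1 bp, on the main arms unless another set of sequences is named. Shares of clusters carry 95% Wilson intervals, which cover counting error only. Overlap of the replicate lists was compared with 100000 circular shifts of replicate 2 within each sequence, on a grid of 100 bp, in a one-sided permutation test. Coverage is the share of bases of a sequence or window that lie in clusters. All bases count, and the share to which reads could be aligned was not determined. The 95% intervals of coverage for a sequence are from 10000 bootstrap draws of windows. Windows were 1 Mb on the main arms and 250 kb on chromosome 4, the heterochromatic sequences and U. An end piece shorter than 50% of a window was left out. Windows of X and of 2L, 2R, 3L and 3R were compared in a two-sided permutation test of 100000 draws. Coverage along each of 5 arms was set against distance from the centromere end with Spearman's rho and a two-sided permutation test. Adjusted p-values are Benjamini-Hochberg values over the family named beside them. The smallest p that 100000 draws can give is 1e-05. Windows and clusters within 1 library are not independent replicates, so no p-value here describes flies in general. Windows within an arm are correlated, and the window tests permuted them singly. Their p-values may therefore be too small even for these libraries.

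Regions are named by a rule fixed beforehand, which takes the 10 longest clusters of the combined list on the main arms that overlap a cluster of both replicates, and the 5 longest clusters of 1 replicate with no overlap in the other. The rule's genes, and 3 planned results on gene features, gene lists and gene length, were not run. They need an annotation of release 5, and the gene table used here is of release 6, so no gene is named from a position and none of the gene lists was tested. The comparison of heterochromatic sequences with arms, the correlation of window coverage between replicates and the ratio of X to autosomal coverage under other settings were added after the data had been seen. So were the reduced input counts and the map of a region of 3R. The comparison of shared with unshared clusters was not among the fixed tests. Nor were the shift tests on single arms, on the heterochromatic sequences and on U.

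The alternatives tried were the highest-scoring 50% of each list, a minimum length, merging of clusters under 1000 bp apart, all sequences in place of the main arms, stricter overlap, random placement in place of shifts, the combined list, windows of 250 kb, chromosome 4 kept among the autosomes, and each replicate alone. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The shift test was tested on simulated data with 100 pairs of lists per setting. It called 4% of unrelated pairs and 100% of pairs in which 5% of clusters were copied. The window test called 6% of simulated draws without a difference and 100% of those with one. That difference was of a single size, close to the one seen on X, and smaller ones were not simulated. The simulated clusters were placed at random and the simulated windows were independent of each other. Real clusters and windows may be grouped along an arm, so these rates need not hold for the real lists. Reduced input counts were recovered for 100% of 2000 simulated scores, and the ratio of their medians was 0.495 where the simulated counts had been set at 50%. The simulated constant lay inside the range searched, so this does not settle the factor of the real lists.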

Results

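H1-enriched clusters were listed for the 2 ChIP replicates of adult fly heads, each with an input sample that the labels tie to its list, and for the replicate set as a whole. Replicate 1 had 2771 clusters covering 4.61 Mb and replicate 2 had 2922 clusters covering 5.24 Mb. The combined list held 15736 clusters covering 29.5 Mb. The median length was 1525 bp in replicate 1, 1592 bp in replicate 2 and 1542 bp in the combined list, not far above the shortest cluster of 1301 bp in both replicates and 1001 bp in the combined list. The median fold enrichment, from the authors' scores, was 1.58, 1.54 and 1.36 in the same order. The longest cluster measured 7087 bp in replicate 1, 8631 bp in replicate 2 and 16359 bp in the combined list. The sequencing depth behind the lists is unknown, and with 1 ChIP group of 2 replicates no test between conditions was possible.

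The series maps H1 along the genome of head nuclei, so the first comparison was among chromosome arms. In the replicates, H1 clusters covered from 2.46% to 4.63% of each of the large autosomal arms 2L, 2R, 3L and 3R. They covered far less of X and of chromosome 4, the small and largely heterochromatic autosome. Together the large autosomal arms were covered to 3.57% ± 0.548 (SD, n = 2 replicates) and X to 0.835% ± 0.109 (SD, n = 2 replicates). Chromosome 4 was covered to 0.308% in replicate 1, by 3 clusters, and to 0.791% in replicate 2, by 7 clusters. The order of the 4 large arms differed between replicates. In replicate 1, 3R had the highest coverage at 4.63% (95% bootstrap interval over windows 4.08 to 5.25) and 2L the lowest at 3.54% (3.11 to 4.00). In replicate 2, 2L had the highest at 3.68% (3.01 to 4.36) and 2R the lowest at 2.46% (2.01 to 2.91). The combined list covered 24.3% of 2L, 20.8% of 2R, 23.4% of 3L, 24.2% of 3R, 7.65% of X and 3.96% of chromosome 4, on which it placed 37 clusters.

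**Figure D1:**
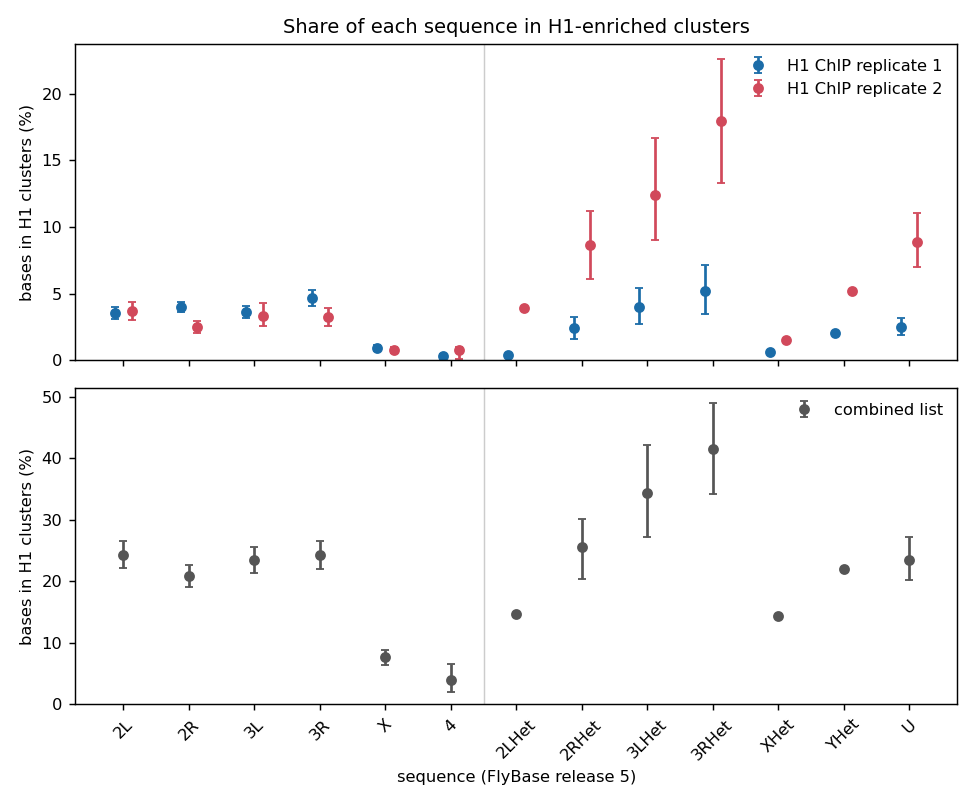
Share of each sequence that lies in H1 clusters, in percent, for the 2 replicates in the upper panel and the combined list in the lower panel, with 95% bootstrap intervals over windows where a sequence has more than 1 window. X and chromosome 4 lie below the large autosomal arms in all 3 lists, and 3RHet is at 5.19% in replicate 1 and 18.0% in replicate 2.

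X carried much less H1 coverage than the large autosomal arms in both replicates. The ratio of X to autosomal coverage was 0.230 in replicate 1, 0.238 in replicate 2 and 0.329 in the combined list. Among the highest-scoring 50% of clusters it was higher, at 0.458 in replicate 1, 0.564 in replicate 2 and 0.755 in the combined list. Over 1-Mb windows, coverage was 0.822% ± 0.469 (SD, n = 22 windows) on X and 3.59% ± 1.29 (SD, n = 97 windows) on the large autosomal arms. The difference of -2.77 percentage points had a p of 1e-05 in a two-sided permutation test, the smallest that 100000 draws can give. It was -3.05 points in replicate 1 and -2.49 points in replicate 2, so it exceeded the spread between replicates, and it was -0.798 points (p = 2e-05, permutation test) among the highest-scoring 50% of clusters. X clusters had a higher median score than autosomal clusters of the same list, by 0.20 in replicate 1, 0.15 in replicate 2 and 0.14 in the combined list, on the log2 scale. A filter on score therefore favours X clusters. They also rested on smaller reduced input counts, with a median of 31.2 per kb on X and 63.2 per kb on the large autosomal arms in replicate 1, and 37.7 and 76.1 per kb in replicate 2.

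Within arms, H1 coverage rose with distance from the centromere end on 3R, and 2L, 2R, 3L and X showed no trend that passed the test in the mean of the replicates. On 3R, Spearman's rho was 0.57 over 28 windows (adjusted p = 0.00925 over 5 arms, two-sided permutation test, Pearson's r = 0.56). It was 0.49 without the 2 windows at the ends of the arm. The 3 windows next to the centromere end of 3R averaged 2.76% and the 3 at the telomere end averaged 5.02%. The values of rho on the other arms were 0.054 on 2L, 0.28 on 2R, -0.04 on 3L and 0.065 on X, with adjusted p-values from 0.546 to 0.852. The windows of 3R from 23 to 24 Mb and from 24 to 25 Mb were among the 6 most covered, with 9.85% and 6.99% in replicate 1 and 5.66% and 5.11% in replicate 2. On 3L the 2 windows nearest the centromere, from 23 Mb to the end of the arm, had 4.23% and 4.21% in replicate 1 and 11.0% and 10.6% in replicate 2. Replicate 1 decided the 3R trend, since rho was 0.65 in replicate 1 alone (adjusted p = 0.00135) and 0.37 in replicate 2 alone (adjusted p = 0.283, permutation tests). On 3R it did not pass in the combined list either (rho = 0.39, adjusted p = 0.0996). On 2L the trend passed in replicate 1 alone (rho = 0.52, adjusted p = 0.0295, permutation test) and turned to -0.27 in replicate 2 alone, where it did not pass (adjusted p = 0.521, permutation test).

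**Figure D2:**
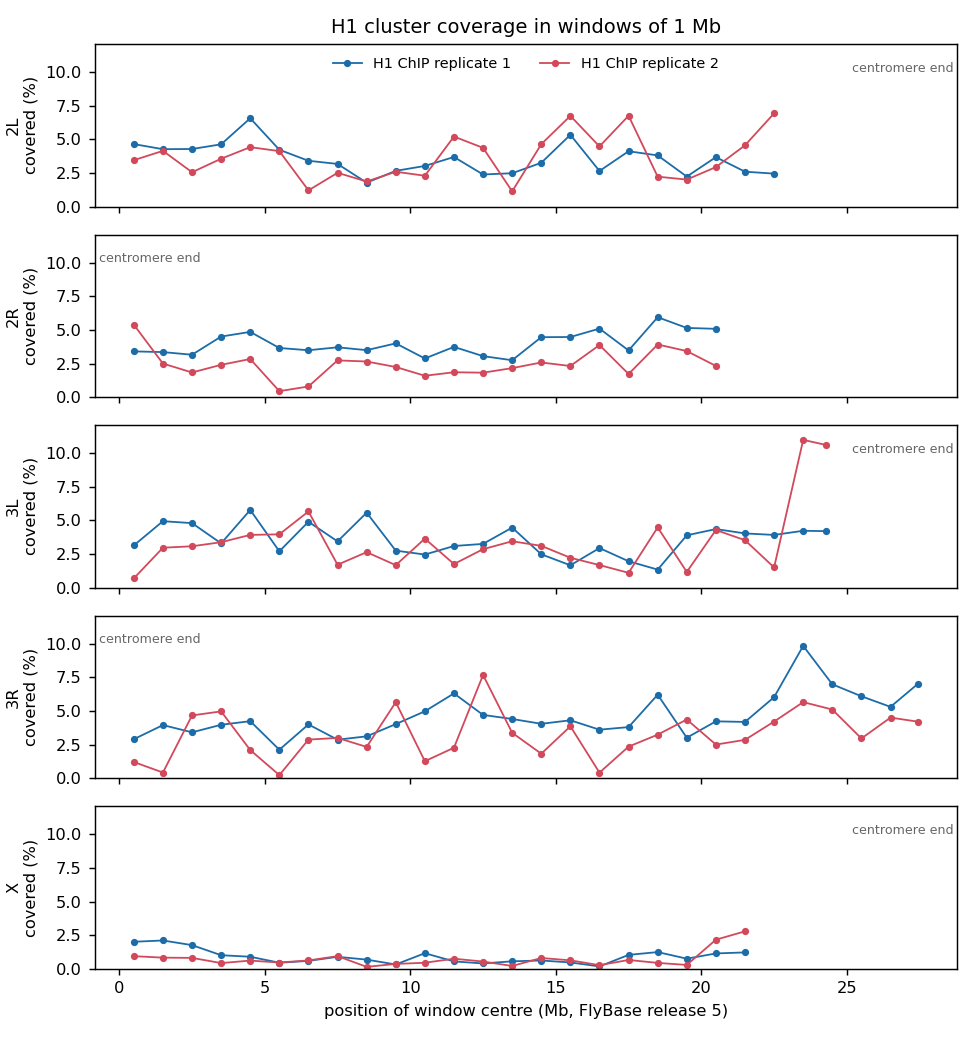
H1 cluster coverage, in percent, of 1-Mb windows along 2L, 2R, 3L, 3R and X, against window position in Mb, with 1 line per replicate. X stays low along its length, and the 2 windows at the centromere end of 3L reach 11.0% and 10.6% in replicate 2 while replicate 1 stays at 4.23% and 4.21%.

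Heterochromatic sequences differed between the replicates more than any arm did. Together they were covered to 11.7% in replicate 2 and 3.45% in replicate 1. In replicate 2 they were covered 3.69 times as densely as the large autosomal arms, and in replicate 1 0.871 times as densely. Such ratios count every base, also any to which reads could not be aligned, so they are not ratios of H1 level. Among the highest-scoring 50% of clusters the ratio was 7.18 in replicate 2 and 1.29 in replicate 1, where it turned. The test was on coverage of 250-kb windows and not on the ratio, and it passed in replicate 1 in that setting (adjusted p = 0.0463, permutation test). Heterochromatic clusters had higher median scores than autosomal clusters of the same list, by 0.084 in replicate 1 and 0.091 in replicate 2. A filter on score therefore favours them, and the turn in replicate 1 cannot be told apart from that selection. Coverage was 18.0% in replicate 2 and 5.19% in replicate 1 on 3RHet, 12.4% and 3.99% on 3LHet, 8.64% and 2.37% on 2RHet, 3.90% and 0.380% on 2LHet, 5.23% and 2.06% on YHet, and 1.54% and 0.641% on XHet. On U, which holds sequence not placed on a chromosome, it was 8.89% in replicate 2 and 2.48% in replicate 1. Clusters on heterochromatic sequences and U made up 33.9% of the list in replicate 2 and 12.3% in replicate 1. Uextra, with a length of 29.0 Mb in the headers, held no cluster in any of the 3 lists. In windows of 250 kb, replicate 2 had 12.0% ± 7.50 (SD, n = 36 windows) on heterochromatic sequences and 3.19% ± 3.08 (SD, n = 387 windows) on the large autosomal arms, a difference of 8.78 points (adjusted p = 2e-05 over 2 replicates, two-sided permutation test). Replicate 1 had 3.52% ± 2.57 and 3.96% ± 2.36, a difference of -0.442 points that did not pass (adjusted p = 0.286, permutation test). The difference between replicates was itself tested and came to 9.23 points (p = 1e-05, two-sided permutation test, the smallest that the draws can give). In the combined list 3RHet was covered to 41.5%, 3LHet to 34.3%, 2RHet to 25.6%, YHet to 22.0%, 2LHet to 14.7% and XHet to 14.4%, and U to 23.5%. Together the heterochromatic sequences were covered 1.35 times as densely as the large autosomal arms in that list.

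The replicates were then compared cluster by cluster, as the only measure of error in the design. On the main arms, 335 of 2431 clusters of replicate 1 (13.8%, 95% Wilson interval 12.5 to 15.2) overlapped a cluster of replicate 2. In the other direction, 338 of 1932 clusters of replicate 2 overlapped (17.5%, 15.9 to 19.3). The bases in both lists were 5.10% of those in either. This overlap was small, yet above that of shifted positions on 2L, 2R, 3L, 3R, X, the heterochromatic sequences and U. On the main arms together 353.6 kb were in both lists and 123 kb ± 11.8 (SD over 100000 shifts) after shifting, a 2.87-fold excess (p = 1e-05, one-sided permutation test, the smallest that the draws can give). The excess was 2.59-fold on 2L, 3.32-fold on 2R, 2.41-fold on 3L, 3.05-fold on 3R, 6.53-fold on X, 2.81-fold on the heterochromatic sequences and 4.29-fold on U, with adjusted p-values from 3.5e-05 to 5e-05. On X the excess rested on 10 of 133 clusters of replicate 1. The shifts moved clusters over all bases of a sequence, also over any to which reads could not be aligned. Such bases lower the shifted overlap, so the excess can hold a bias that the replicates share. On the heterochromatic sequences 105 of 192 clusters of replicate 1 (54.7%, 47.6 to 61.6) overlapped replicate 2, and 109 of 551 clusters of replicate 2 (19.8%, 16.7 to 23.3) overlapped replicate 1.

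**Figure D3:**
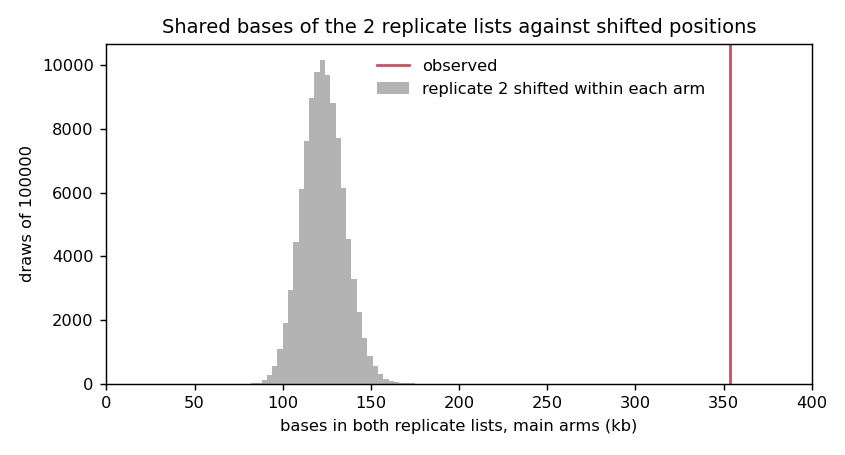
Histogram of the bases, in kb, that lie in clusters of both replicates on the main arms after each of 100000 circular shifts of replicate 2, with the observed value as a vertical line. The observed 353.6 kb lies above all shifted values, whose mean is 123 kb and whose maximum is 220 kb.

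Shared clusters of the main arms were longer than unshared ones in both replicates, and their scores did not differ detectably. Mean length was 1802 bp ± 677 (SD, n = 335) for shared and 1638 bp ± 387 for unshared clusters of replicate 1, and 1825 bp ± 704 (SD, n = 338) and 1658 bp ± 409 in replicate 2 (adjusted p = 2e-05 in both, two-sided permutation test over 4 comparisons). Mean scores were 0.66 and 0.66 in replicate 1 (adjusted p = 0.829) and 0.60 and 0.61 in replicate 2 (adjusted p = 0.756, permutation test). Longer clusters also have more room to overlap. Across the 335 shared clusters, which are not independent replicates, the scores of the replicates were weakly related (Spearman's rho = 0.14, p = 0.00878, Pearson's r = 0.23, p = 2e-05, two-sided permutation tests). On all sequences, heterochromatic and unplaced ones included, rho was 0.38 (p = 1e-05, permutation test). Median scores in replicates 1 and 2 were 0.65 and 0.59 on the large autosomal arms, 0.73 and 0.68 on heterochromatic sequences and 0.81 and 0.81 on U. Pooling these classes can itself raise rho. Where clusters had to overlap by 50% of both lengths the relation did not pass (rho = 0.14, p = 0.0648, permutation test). Coverage of the 97 autosomal windows of 1 Mb was related between replicates with rho = 0.33 (p = 0.00119, two-sided permutation test, Pearson's r = 0.27).

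The combined list held nearly all of the replicate clusters and many more. On the main arms it overlapped 93.5% of the clusters of replicate 1 and 97.3% of those of replicate 2, which is not independent evidence, since the list was made from the same replicates. Of its 15736 clusters on all sequences, 561 (3.57%) overlapped clusters of both replicates, 2009 overlapped replicate 1 alone, 2172 overlapped replicate 2 alone and 10994 (69.9%) overlapped neither. Overlap with both does not mean that the clusters of the replicates overlap each other, and a longer combined cluster has more room to meet both. Clusters that overlapped both replicates had a median length of 3941 bp and a median fold enrichment of 1.41. Those that overlapped neither had 1331.5 bp and 1.35. On heterochromatic sequences and U the order of the fold enrichment was the other way, at 1.47 in both and 1.52 in neither. On X 954 of 1157 clusters (82.5%) and on chromosome 4 30 of 37 clusters (81.1%) were in neither replicate. The combined list holds clusters shorter than any in the replicate lists, and 64.3% of its clusters are at least as long as the shortest replicate cluster.

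The longest clusters of the combined list that overlapped a cluster of each replicate lay on 3R, 2R, 2L and 3L. Inside such a region the clusters of the replicates need not overlap each other. The leading pair were neighbours near the distal end of 3R, at 27312759 to 27329117 (16359 bp, 1.40-fold) and 27329618 to 27345275 (15658 bp, 1.44-fold). Replicate clusters covered 22.3% and 17.3% of the former, in replicates 1 and 2, and 32.2% and 48.4% of the latter. In the former the replicates had no base in common. Replicate 1 had clusters at 27317621 to 27319874 and 27323967 to 27325352, and replicate 2 at 27315974 to 27317347 and 27326419 to 27327872. In the latter, clusters of the replicates did overlap. The third was on 2R at 18590780 to 18604599 (13820 bp, 1.40-fold), with 34.3% and 39.6% covered in replicates 1 and 2. The fourth was on 2L at 629171 to 642112 (12942 bp, 1.39-fold), with 11.3% and 48.1% covered. The others were at 21705451 to 21716360 on 3L, 4631775 to 4642528 on 2L, 27379631 to 27390298 on 3R, 1898110 to 1908299 and 3644628 to 3654774 on 3L, and 19310220 to 19320053 on 3R. These 6 measured from 9834 to 10910 bp with fold enrichments from 1.35 to 1.43. Of the 10 regions, 3 lay within 100 kb of each other on 3R, from 27.3 to 27.4 Mb. That stretch, chosen for a map after its values were seen, was covered to 25.8% in replicate 1 by 12 clusters, to 24.1% in replicate 2 by 13 clusters and to 84.6% in the combined list by 12 clusters.

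All 5 of the longest clusters seen in 1 replicate alone were in replicate 2 and on heterochromatic or unplaced sequence. They lay on 3RHet at 38617 to 45997 (7381 bp, 1.54-fold) and 1462351 to 1468083 (5733 bp, 1.70-fold), on 2RHet at 3012215 to 3018068 (5854 bp, 1.59-fold), and on U at 2871401 to 2877040 (5640 bp, 1.76-fold) and 11107 to 16353 (5247 bp, 1.83-fold).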

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

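Alternatives that kept the longer combined clusters or left out clusters of a reduced input count of 5 or less were chosen after seeing the data, as were those for heterochromatic sequences, for window correlations and for ratios of X to autosomes. A minimum length of 1000 bp removed no cluster, and its 18 values are left out of the counts. Of 145 other alternative values, 49 for the chief results and 36 for the others kept direction and side of the threshold, or moved within their error. The excess of shared bases over shifted positions, the deficit of X and the difference between replicates on heterochromatic sequences kept direction and call under each alternative run for them, but not their size.

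The highest-scoring 50% of each list, smaller by construction, gave means of 1424 clusters and 2635 kb per replicate (2846.5 and 4924 in full). The overlapping shares of replicates 1 and 2 became 6.56% and 10.5% (13.8% and 17.5% in full), shared bases 2.71% of those in either list (5.10%), overlap with the combined list 64.7% and 78.1% (93.5% and 97.3%), combined clusters in either replicate 20.4% (27.9%), and main-arm coverage 1.38% (3.03%). The heterochromatic to arm ratio of replicate 1 turned to 1.29 (adjusted p = 0.0463, permutation test; 0.871 in full), and rho on 3L turned to 0.051. The ratio of replicate 2 became 7.18 (3.69). The X to autosome coverage ratio became 0.511 (0.234, mean of replicates) and the X difference -0.798 points (-2.77). Clusters on X and on heterochromatic sequences had higher median scores than autosomal ones, so this filter favours them in these ratios. Other causes were not tested.

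On all sequences the overlapping share of replicate 1 was 18.3%, shared bases 6.15%, combined clusters in either replicate 30.1% and the score correlation 0.38 (p = 1e-05, permutation test). With 50% of a cluster to be covered, the replicate shares were 8.52% and 11.0%, and those with the combined list 91.9%, 96.1% and 22.0%. With 50% of both clusters, the replicate shares were 7.45% and 9.37%, and the score correlation of 0.14 no longer passed (rho = 0.14, p = 0.0648, permutation test), on fewer clusters. With combined clusters as long as those of the replicates, the shares were 84.9%, 92.9% and 39.9% and main-arm coverage 15.7%. The combined list itself covered 20.2% of the main arms. The X to autosome coverage ratio was 0.329 in it, 0.266 in its longer clusters and 0.220 in the replicates without clusters of a reduced input count of 5 or less.

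The trend along arms depended on the replicate. It passed on 0 to 2 arms with 1 replicate left out, where rho on 2L ran from -0.27 without replicate 1 to 0.52 without replicate 2, and rho on 3L from -0.16 to 0.18. In the combined list it passed on 0 arms, with -0.066 on 2L and -0.049 on X, and with windows of 250 kb rho on X was -0.0096. The cause was not tested. The X to autosome ratio of reduced input count per kb was 0.494 over the replicates, 0.523 in the combined list and 0.520 with the score constant doubled.

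The 3 planned results on gene features, gene lists and gene length, and their alternatives, were not run. No paired analysis was possible because the input samples have no lists of their own here and no result compares groups of samples. Unknown library depth limits the lists: weak clusters missed in 1 replicate cannot be separated from clusters absent in it.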

Other observations

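The tests of explanations below were all chosen after the result they bear on had been seen, as were their bounds. The clusters with the highest scores lay mostly on U. In replicate 1 the leading cluster was on U at 5748053 to 5749995 with a fold of 17.6, from 15 ChIP to 1 input in lowest terms, and in replicate 2 on U at 7200015 to 7201332 with a fold of 11.1, from 10 to 1. The highest fold of the combined list, 13.7, was that of 4 clusters at 12 to 1, of which 3 were on U and 1 on X at 14175948 to 14177946. Clusters with a reduced input count of 5 or less made up 12.8% of those on U in replicate 1 and 8.66% in replicate 2, 8.27% and 9.62% of those on X, 6.25% and 5.63% of those on heterochromatic sequences, and 2.88% and 2.86% of those on the large autosomal arms. Gaps between neighbouring clusters were under 1000 bp in 30.0% of cases in the combined list, which has the most clusters, in 5.77% in replicate 1 and in 8.01% in replicate 2. The median gap was 2366 bp, 23867 bp and 13243 bp in the same order.

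X was covered less than the large autosomal arms, and fewer reads on X are a candidate explanation that the tables do not decide. Longer clusters of the combined list covered 1.36 times as much of X as replicate clusters covered of the large autosomal arms, but that list covered 5.13 times as much of the autosomal arms too, so the comparison has no weight, and a lower H1 level on X cannot be told apart from fewer reads. An excess of male flies, which have a single X, may lower the reads: the X to autosome ratio of reduced input counts per kb, which stand in for reads and are not DNA doses, was 0.523 (95% interval 0.495 to 0.541), where equal sexes would give a DNA dose of 0.75. Heterochromatic sequence, most of it autosomal, had 0.516 (0.481 to 0.549) in the combined list, but 0.638 (0.533 to 0.741) and 0.643 (0.574 to 0.727) in replicates 1 and 2, above 0.494 (0.431 to 0.536) and 0.495 (0.337 to 0.593) on X with overlapping intervals, so an excess of males and a choice of low-input regions by the call cannot be told apart. No biological explanation was tested, since no group separates the sexes.

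Chromosome 4 had the lowest coverage of the main arms in replicate 1 and the combined list, although much of it is heterochromatic. In the combined list its 37 clusters had 1.21 times the reduced input counts per kb of the large autosomal arms (0.990 to 1.28), which gives no sign of fewer reads where clusters were called. The ratio was 0.807 (0.058 to 1.28) in replicate 1, from 3 clusters, and 0.169 (0.143 to 0.528) in replicate 2, from 7 clusters. Fewer reads and less H1 cannot be told apart here, since clusters cover 3.96% of the chromosome at most and the rest was not seen. No biological explanation was tested.

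The relative coverage of heterochromatic sequences was 4.23 times as high in replicate 2 as in replicate 1. A more permissive call over the whole genome, with all else equal, is argued against. The large autosomal arms had 0.804 times the covered bases in replicate 2 while heterochromatic sequences had 3.40 times. Depth is unknown, however. Median scores were lower in replicate 2 than in replicate 1, at 0.59 and 0.65 on the large autosomal arms and 0.68 and 0.73 on heterochromatic sequences. A more permissive call beside a difference in depth is therefore not excluded. Clusters of low reduced input count did not carry the difference. The fold was 4.28 without clusters of a reduced input count of 5 or less and 4.36 without those of 20 or less. Those of 5 or less were only 6.25% of heterochromatic clusters in replicate 1 and 5.63% in replicate 2. The cutoffs rest on a constant known only up to a factor, so few input reads as such are not excluded. Less heterochromatic DNA in the input of replicate 2 stays open and cannot be told apart from more H1: the heterochromatic to arm ratio of reduced input counts in replicate 2 was 1.01 times that of replicate 1 (0.839 to 1.25), too wide to exclude a small deficit. The replicates are 1 group, so no biological explanation was tested, and a difference in chromatin preparation or in the flies collected may also underlie it.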
